A study of Mus musculus with 6 samples.

How the data were processed

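Droplet-based single cell RNA sequencing was done on peripheral blood mononuclear cells of C57BL/6J mice, isolated on a Histopaque density gradient with lysis of red cells, per the labels' protocols. The 3 wild type control libraries were used, and the knockout libraries were not analysed here. The deposited values were counts, unnormalized UMI counts per gene and barcode for 32285 genes, in 1 matrix per library. Cell Ranger 6.1.2, R 4.3.1 and Seurat 4.4.0 are named in the submitters' processing notes, which also name the builds mm10 and GRCh38 without a role. The settings used to tell cells from empty droplets are not given in the sources used here. The lowest count of any barcode was 500 UMIs in each library.

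The libraries held 68336 barcodes in all, with medians of 1162, 1119 and 1006 genes in control 1, 2 and 3. Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, 20785, 21445 and 23246 of them. Scrublet, run per library with an expected rate of 0.06, called 2337, 1861 and 3454 doublets (11.2%, 8.68% and 14.9%), which were removed. That left 57824 cells, 18448, 19584 and 19792 per library. The libraries were compared with each other before averaging. A chi-square of their gene totals gave 919, 475 and 230 per degree of freedom for the 3 pairs, so none was a copy of another. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

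Counts were scaled to the same total per cell and logged. The 2000 most variable genes within libraries were taken among genes seen in at least 20 cells. Genes of the fixed lists, immunoglobulin and T cell receptor variable genes, Xist and Y-linked genes were left out of them. From 30 principal components a shared-neighbour graph with 15 neighbours was built and divided by the Leiden method at resolution 1 with seed 1, giving 33 clusters. A cluster was named from 103 fixed marker genes. For each class the score was the mean log2 ratio of the marker CPM in the cluster to the median over clusters, with a prior of 10 CPM. A name needed a score of at least 2.5, or 2 for T cell subsets, and at least 3 markers detected in at least 10% of cells. A cluster stayed unnamed where a second class scored at least 2 and over 0.5 of the best score, or at least 2.5. These naming thresholds were set after the clusters had been seen, and the marker genes before. They gave 20 named clusters in 14 classes and left 13 clusters with 2940 cells unnamed, 2.11%, 7.49% and 5.47% of the cells of control 1, 2 and 3. Names are written as "like" because they rest on these markers.

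Counts were summed per class and library, for classes with at least 20 cells in each library. Genes were tested with edgeR 4.0.16 (quasi-likelihood test, trimmed mean of M values scaling, its low-count filter), with the library as a block, two-sided, and Benjamini-Hochberg adjustment at 0.05. Both classes of a comparison come from the same library, which is where the pairing comes from. Standard errors are the size of the log2 difference divided by the square root of the F statistic of its test. Fitted differences use scaled library sizes, so a ratio of printed CPM can differ from them. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists with at least 3 measured genes. None of the list calls held with the estimated correlation. The p-values rose also for lists whose estimated correlation was under 0.01, so these losses do not measure correlation alone. The 12 lists, 271 genes in all, covered chemokine and sphingosine phosphate receptors, adhesion molecules, class II and class I presentation, type I interferon response, inflammatory cytokines and NF-kB feedback, phagocytic, Fc and complement receptors, survival and growth factor receptors, lipid handling, cytotoxic effectors, transcription factors of leukocyte subsets, and immediate early and heat shock genes. Mx1, Mx2 and Clec7a of the lists and Ahsp of the markers were not found by symbol. Comparisons, lists, markers, the rule for named genes and most alternatives were fixed before the data were examined.

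Named genes were chosen by rule, and a few that it takes are not reported here. They are Cx3cr1, the list members with the smallest adjusted p (up to 2 per list in the monocyte comparison and 1 in the others), and the largest differences in each direction (5 in the monocyte comparison, 4 in the others) among genes that passed, averaged at least 20 CPM and were neither markers nor used for clustering. Other list members are given as examples of their list and were chosen after their values were seen, as were the T cell, B cell and haemoglobin genes named beside the lists. A gene with 0 counts in a class is given as a bound against 3 counts over the class, and one with 1 to 3 counts as a ratio with its counting interval. With such genes at their bounds, the medians of their lists keep their values. H2-Q6, H2-Q7, H2-K1, H2-D1, Bcl2a1a, Bcl2a1b and Ifi209 have close copies and are uncertain as single genes. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, leaving shallower cells out. Intervals are exact Poisson for counts and exact binomial for shares, at 95%, and cover counting error only.

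The summed profiles held 489251 to 16024204 UMIs. The test was tested on simulated counts with 200 changed genes per comparison. In the monocyte simulation it recovered 65.2%, 90.8% and 100% of genes changed 1.5-fold, 2-fold and 4-fold and called 8 of 8824 unchanged genes (9047 genes tested). The corresponding values were 15.4%, 56.9% and 90.9% for neutrophil-like against classical-like (4 of 7992 called, 8218 tested), 73.1%, 94% and 100% for NK-like against CD8 T-like (10 of 10089, 10316 tested) and 79.1%, 94% and 98.4% for CD8 against CD4 T-like (8 of 10402, 10630 tested). The interferon list, moved 2-fold down, was called in 4 of 4 simulations, and 1 unmoved list was called in the simulation of NK-like against CD8 T-like cells. Genes were drawn independently of each other, so the simulations do not show how correlation among list genes affects the list calls.

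Alternatives were DESeq2 1.42.0 (Wald test), median-ratio (RLE) scaling, no low-count filter, no replicate block, all named classes in 1 fit, a stricter cell filter (500 genes, 5% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2, leaving out each library in turn, and a count split. In the count split a random part of the UMIs, drawn with probability 0.5, was used for clustering and the rest for testing. The fit with no replicate block was added for the gene lists after seeing the data. Gene positions come from GENCODE vM21 on GRCm38, in which 32235 of the 32285 gene identifiers were found (99.8%). The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3.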

Results

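Single cell RNA sequencing measured the transcripts of peripheral blood mononuclear cells, the lymphocytes and monocytes that a density gradient separates from whole blood, in C57BL/6J mice. The series sets wild type mice against mice in which Cx3cr1 was deleted in monocytes and macrophages. The wild type group had 3 libraries, called control 1, 2 and 3 here. The knockout libraries were not analysed here, so no difference between knockout and wild type is given. Every comparison below is between cell classes within the same 3 control libraries. The libraries held 21324, 22792 and 24220 barcodes with 84397981, 90710982 and 75373903 unique molecular identifiers (UMIs), a median of 3328.5, 3238 and 2590 UMIs per barcode.

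Cx3cr1 encodes the receptor for fractalkine, a chemokine made by endothelium and neurons, and is the gene deleted in the knockout group. It was read out first, in every library and class. In the nonclassical-like monocytes of control 2 and 3 it stood at 358 and 350 CPM, UMIs of the gene scaled to a common total per class and library, from 1247 and 951 UMIs. In the library labelled control 1 the same class held 8 UMIs, or 4.82 CPM (95% exact Poisson interval 2.08 to 9.50). The mean over the 3 libraries was 238 ± 202 CPM (SD, n = 3). Classical-like monocytes showed the same split, with 12.4 CPM in the library labelled control 1 and 76.6 and 83.3 CPM in control 2 and 3. NK-like cells did not: they held 48.2, 49.5 and 43.4 CPM, a mean of 47.1 ± 3.22 (SD, n = 3). Conventional dendritic-like cells held 52.4, 95.8 and 82.8 CPM, and CD8 T-like cells 4.78, 14.98 and 8.99 CPM. B-like cells, which served as background, held 0.0477, 1.26 and 1.18 CPM. The Cx3cr1 level of the library labelled control 1 thus goes against its label in monocyte-like cells and not in NK-like cells. It stays in its labelled group throughout, and each count of differing genes is also given without it.

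The gene (ENSMUSG00000052336) lies on chromosome 9 of GRCm38, from 119901616 to 120069879 on the minus strand, and is protein coding with 3 annotated transcripts. Transcript Cx3cr1-201 has 2 exons. Its coding sequence, 120051273 to 120052334, and its long 3′ untranslated part, 120048683 to 120051272, share the exon from 120048683 to 120052343. Tags of a 3′ assay fall mostly near the end of a transcript. The part removed in the knockout animals is not given in the sources used here, and a tag outside a deleted part checks nothing.

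After each cell was thinned to 1000 UMIs, 1.13%, 29.2% and 27.8% of nonclassical-like cells had a Cx3cr1 UMI in control 1, 2 and 3. Unthinned shares were 1.96%, 63.7% and 51.8%. In B-like cells the thinned shares were 0 of 7700 cells, which allows up to 0.0390%, then 0.152% and 0.111%. NK-like cells had 4.35%, 4.70% and 3.48%, and classical-like monocytes 0.338%, 6.70% and 8.13%. Median depths before thinning were 3883, 3315.5 and 2159 UMIs in nonclassical-like and 2375, 2157 and 1744 in B-like cells, and 4, 31 and 44 nonclassical-like cells and 72, 34 and 141 B-like cells were too shallow to enter. Intervals and zero limits cover counting error only.

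With all classes in 1 fit, Cx3cr1 was higher in nonclassical-like monocytes than in each of 12 other classes tested. The log2 difference was 7.98 (SE 0.49) from B-like, 4.16 from CD8 T-like, 2.11 from NK-like and 1.75 from classical-like cells (SE 0.31; adjusted p = 1.13e-05). In the library labelled control 1 conventional dendritic-like cells held 10.9 times and NK-like cells 10.0 times the level of nonclassical-like monocytes. The levels there of classical-like monocytes (12.4 CPM, exact Poisson interval 7.99 to 18.2), basophil-like cells (11.5 CPM from 2 UMIs, 1.39 to 41.4) and proliferating cells (8.43 CPM, 4.04 to 15.5) had intervals that overlap that of nonclassical-like monocytes. Lower levels with overlapping intervals were seen there in CD8 T-like (4.78 CPM, 3.76 to 5.99) and regulatory T-like cells (2.48 CPM, 0.301 to 8.97). The same held for neutrophil-like (2.04 CPM, 0.0517 to 11.4) and gamma-delta T-like cells (0 UMIs, up to 13.3 CPM). The difference from NK-like cells was 3.09 without that library and 1.24 without control 3. The difference from CD8 T-like cells was 3.48 without control 3. No UMI of the gene was seen in plasmacytoid dendritic-like or erythroid-like cells, so over the summed libraries nonclassical-like monocytes were at least 46.2-fold and at least 112-fold higher, against a floor of 3 counts over the class. Without control 2 these bounds were 20.8-fold and 6.96-fold, and without control 3 the first was 29.1-fold. In the library labelled control 1 the 4.82 CPM of nonclassical-like monocytes lay below the limits that a count of 0 allows there, 20.04 CPM in plasmacytoid dendritic-like and 97.5 CPM in erythroid-like cells, so no difference was detectable in it. Without control 2 the call held for 8 of the 12 classes and was lost for basophil-like (adjusted p = 0.216), conventional dendritic-like (0.146), gamma-delta T-like (0.0513) and plasmacytoid dendritic-like cells (0.0504). Without control 3 it held for 9, and was lost for conventional dendritic-like (0.285), gamma-delta T-like (0.0580) and NK-like cells (0.0966).

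**Figure D1:**
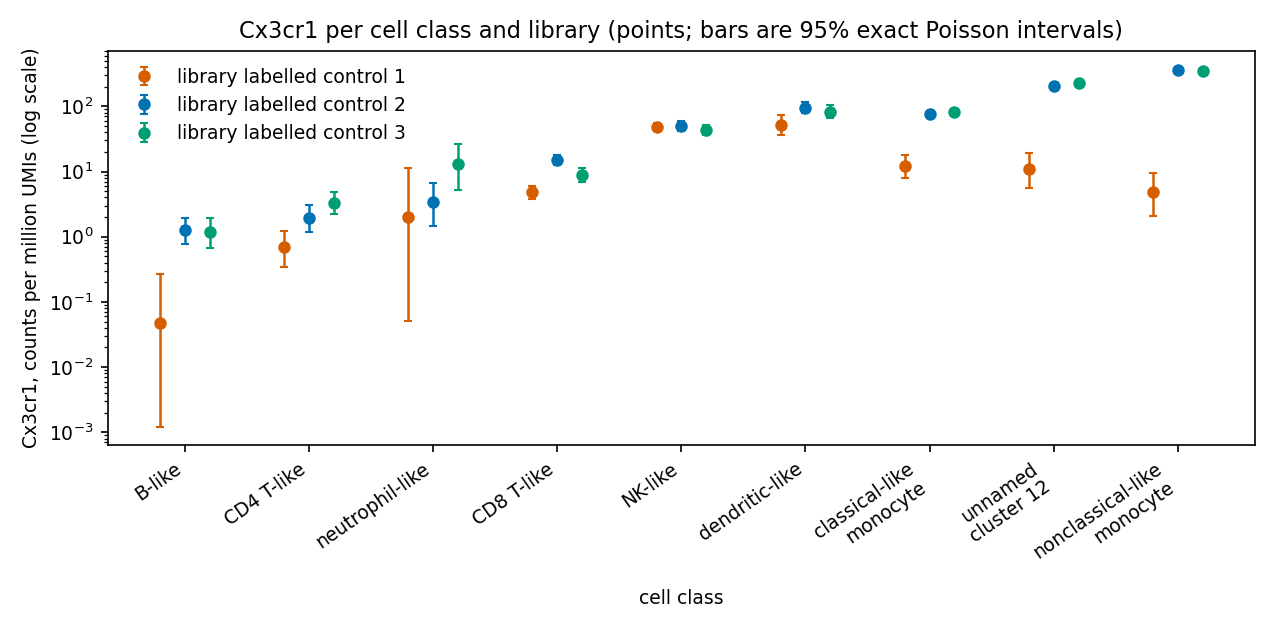
Cx3cr1 in CPM on a log axis for each cell class, 1 point per control library with its 95% exact Poisson interval. In nonclassical-like monocytes control 2 and 3 sit at 358 and 350 CPM and the library labelled control 1 at 4.82 CPM, while the NK-like points lie between 43.4 and 49.5 CPM.

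B-like cells were the most frequent class, at 42.1%, 33.8% and 32.6% of kept cells in control 1, 2 and 3 (mean 36.2% ± 5.20, SD, n = 3). CD4 T-like cells made up 18.2% ± 3.81, CD8 T-like cells 14.0% ± 2.82 and NK-like cells 6.96% ± 1.60. Classical-like monocytes ranged widely, with 1.62% (exact binomial 95% interval 1.44 to 1.81), 11.4% and 14.4% (mean 9.15% ± 6.69). Nonclassical-like monocytes made up 1.94%, 3.99% and 4.88% (3.60% ± 1.51) and neutrophil-like cells 0.894%, 6.79% and 1.93% (3.20% ± 3.15). Regulatory T-like cells held 1.36% ± 0.166. Basophil-like, proliferating, dendritic-like, erythroid-like and gamma-delta T-like cells each averaged under 1%. At Leiden resolution 2 gamma-delta T-like cells, 0.208% here, made up 2.32%, and erythroid-like cells, 0.276% here, made up 0.610%, with 0.632% at resolution 0.5 and 0.586% with doublets kept. The gradient and the lysis of red cells, both in the labels' protocols, can set the shares of neutrophil-like and erythroid-like cells. No test was made between libraries, since they belong to 1 group.

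**Figure D2:**
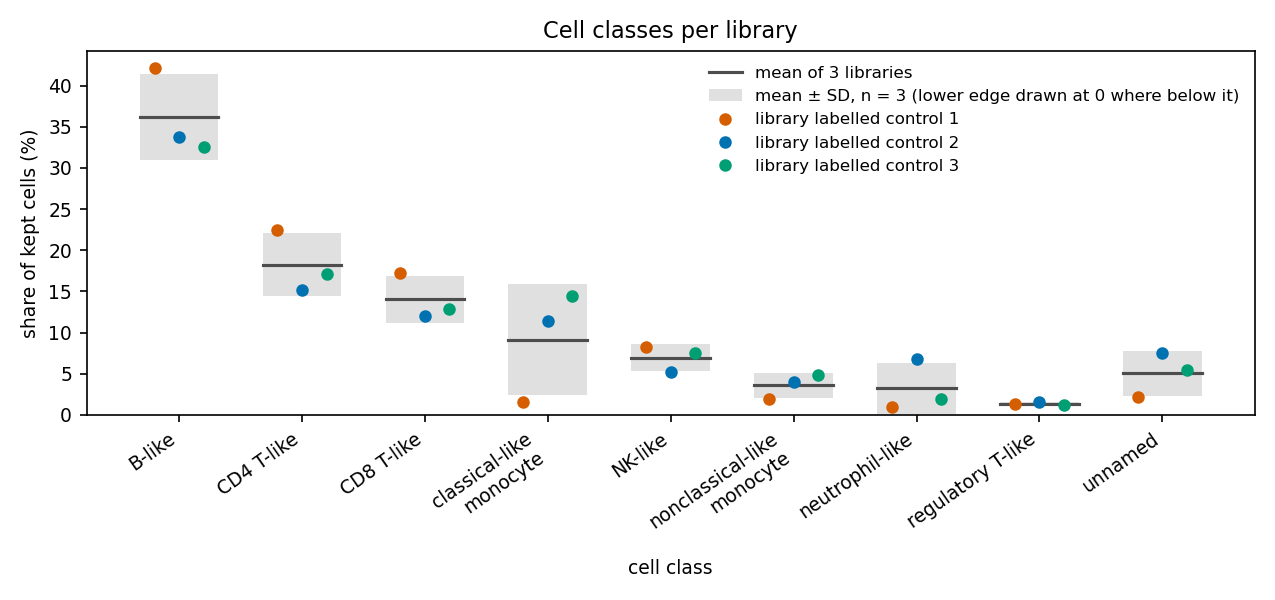
Share of kept cells in each class, in percent, with 1 point per control library, the mean as a line and the mean ± SD over 3 libraries in grey. B-like cells average 36.2%, and classical-like monocytes spread from 1.62% in the library labelled control 1 to 14.4% in control 3.

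Blood monocytes come in 2 main kinds, the classical cells that enter inflamed tissue and the nonclassical cells that patrol vessel walls, and the deletion in this series is of a receptor gene of these cells. Nonclassical-like monocytes held far more Fabp4, a lipid chaperone, at 467 ± 76.1 CPM against 0.927 ± 0.835 in classical-like monocytes (SD, n = 3; log2 difference 8.43, SE 0.18; adjusted p = 2.86e-10). They also held more Cd36, a scavenger receptor for oxidised lipoproteins (log2 6.67, SE 0.15), and Itgax, the integrin chain CD11c, at 123 ± 10.6 against 1.89 ± 0.929 CPM (log2 6.13, SE 0.17). Classical-like monocytes held more Ccr1, a chemokine receptor (log2 -7.19, SE 0.21), Ccr2, the receptor that takes monocytes out of bone marrow (-4.98, SE 0.12), and Isg15, an interferon-induced ubiquitin-like protein, at 129 ± 15.4 against 12.1 ± 2.55 CPM (-3.59, SE 0.13). Each of these genes differed the same way in 3 of 3 libraries. At Leiden resolution 0.5 the difference was 5.52 for Fabp4 (7.23 with the stricter cell filter), 4.82 for Cd36 and 4.61 for Itgax, and in the count split it was -5.74 for Ccr1 and -3.95 for Ccr2. Cx3cr1 was higher in nonclassical-like monocytes by 1.81 (SE 0.26; adjusted p = 1.75e-04) but in 2 of 3 libraries, since the library labelled control 1 had the higher level in classical-like monocytes, with overlapping counting intervals. The Cx3cr1 call was lost with DESeq2 (0.98, adjusted p = 0.494) and with no replicate block (1.80, adjusted p = 0.101). Its adjusted p ranged from 7.54e-132 to 0.494 over the alternatives. The lowest value came from edgeR without the library labelled control 1, a fit that rests on fewer profiles than the main one.

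The strongest group was the type I interferon response. Of its 29 measured genes, 27 were lower in nonclassical-like monocytes and 2 did not pass, Irf9 among them (-0.27, and past the threshold without control 3, at -0.45), with 27 called when adjusted over the list alone. The median was -1.35, and the list ranked below other genes (adjusted p = 3.87e-13; adjusted p = 0.788 with an estimated correlation). Examples beside Isg15 were Slfn5 (-3.45) and Ifi209 (-2.72, SE 0.09), a DNA sensor of a family of close copies whose counts are uncertain. Among inflammatory cytokines and NF-kB feedback genes, 11 of 20 were lower, 4 higher and 5 did not pass (15 called when adjusted over the list alone). The chemokines Ccl2 (-4.35), Cxcl2 (-2.52) and Ccl9 (-2.28) were lower and the cytokine gene Il1b (1.30) higher. That list's adjusted p was 0.0509, and 0.0242 without control 2, 0.0291 without control 3 and 0.0324 with no replicate block.

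Among chemokine and sphingosine phosphate receptors, 6 of 11 were higher, 4 lower and 1 did not pass (10 when adjusted over the list alone), led upward by S1pr5 (5.21) and Cxcr4 (2.13). The median was 0.78 and the mean -0.38 (adjusted p = 0.980). Of 17 adhesion molecules 8 were higher, 5 lower and 4 did not pass (13 when adjusted over the list alone; adjusted p = 0.246). Pecam1, the junctional protein CD31 (4.44, with 3.79 at Leiden resolution 0.5 and 3.76 in the count split), and Itgal (2.70), a chain of LFA-1, were higher, while Itga1, another integrin chain, was lower (-4.37). The adhesion list passed without control 2 (adjusted p = 0.00691) and with no replicate block (0.00965).

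The class II genes split. Of 9 measured, 3 were higher, 3 lower and 3 did not pass (7 when adjusted over the list alone), with a median of 0.39, a mean of -0.23 and a test pointing down (adjusted p = 0.738). Cd74, the invariant chain (0.89), and H2-Aa (0.69) were higher, and H2-DMa (-2.37) and H2-DMb1 (-1.77), which load peptides, lower. Whether the higher Cd74 and H2-Aa values are the cells' own RNA was not tested. The H2-Aa call was lost without control 2 (0.33). Of 15 class I genes 7 were higher, 5 lower and 3 did not pass (12 when adjusted over the list alone; adjusted p = 0.247). H2-Q7 (2.64), H2-Q6 (3.56) and H2-K1 (1.16) share sequence with each other, so their single values are uncertain, and H2-Q7 was at 1.95 at Leiden resolution 0.5. Phagocytic, Fc and complement receptors were higher for 6 of 19, lower for 10 and did not pass for 3 (16 when adjusted over the list alone; adjusted p = 0.247). Fcgr4, an activating IgG receptor (3.70), was higher, Fcgr1 (-2.60) lower, and Mrc1 had no count in nonclassical-like monocytes, at least 16.8-fold higher in classical-like ones against a floor of 3 counts over the class, and at least 8.10-fold without control 2.

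Survival and growth factor receptor genes were higher for 9 of 21, lower for 7 and did not pass for 5 (16 when adjusted over the list alone; adjusted p = 0.246). The antiapoptotic Bcl2a1b (6.13) and Bcl2a1a (5.95) are near-identical copies and uncertain as single genes, with 4.34 and 4.3002 at Leiden resolution 0.5, and Bcl2 was higher by 2.91. The list passed without control 2 (adjusted p = 0.00124) and with no replicate block (0.00694). Lipid handling genes were higher for 11 of 23, lower for 8 and did not pass for 4 (20 when adjusted over the list alone; adjusted p = 0.247), with the nuclear receptors Pparg (5.76) and Nr1h3 (4.53) higher and Npc2, a lysosomal cholesterol carrier, lower (-2.04). It too passed without control 2 (0.0242) and with no replicate block (0.00965).

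Transcription factors were higher for 12 of 26, lower for 10 and did not pass for 4 (22 when adjusted over the list alone; adjusted p = 0.714). Nr4a1, on which nonclassical monocytes depend, was higher by 1.77 (SE 0.09), as were Klf4 (1.26) and Klf2 (1.64), and Maf was lower (-1.78). The lymphocyte factors Lef1 (1.44), Tcf7 (1.81) and Ikzf3 (3.84) were also higher, and so were the T cell markers Cd3d (1.52) and Trac (1.63). Whether these higher values are the cells' own RNA was not tested. Without control 3 Tcf7 was at 2.45 and Ikzf3 at 3.20. Immediate early and heat shock genes were higher for 9 of 22, lower for 10 and did not pass for 3 (19 when adjusted over the list alone; adjusted p = 0.361), with Ier3 (-2.90) and Egr1 (-2.47) lower. Of 5 cytotoxic effector genes measured, Lamp1 was lower (-0.59), Srgn, the core protein of granule proteoglycans, higher (0.14, adjusted p = 0.0189), and 3 did not pass (2 when adjusted over the list alone; median -0.08; adjusted p = 0.714). The Srgn call was lost in 6 alternatives, among them without control 2 (adjusted p = 0.191) and without control 3 (0.0867), over a range of 0.0867 to 0.601.

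Outside the lists, markers and clustering genes, the largest differences upward included Tgfbr3, a coreceptor of transforming growth factor beta (6.27), and Tmem26 (6.22). Downward they included Prtn3, a granule protease (-6.84), Gas7 (-5.13) and Mmp19, a matrix metalloproteinase (-4.93). At Leiden resolution 0.5 the values were 4.69 for Tgfbr3, 5.33 for Tmem26 and -6.21 for Prtn3. In the count split they were 5.52 for Tmem26, -5.99 for Prtn3, -4.12 for Gas7 and -4.04 for Mmp19. In all, 5121 of 9075 genes tested differed, 2538 higher and 2583 lower in nonclassical-like monocytes, and 1708 of them by at least 2-fold. Without the library labelled control 1 the count was 5994. The summed profiles held 1659384 to 13569263 UMIs, and the classes came from clusters of the same cells, so the counts rest on both the clustering and these 3 libraries.

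**Figure D3:**
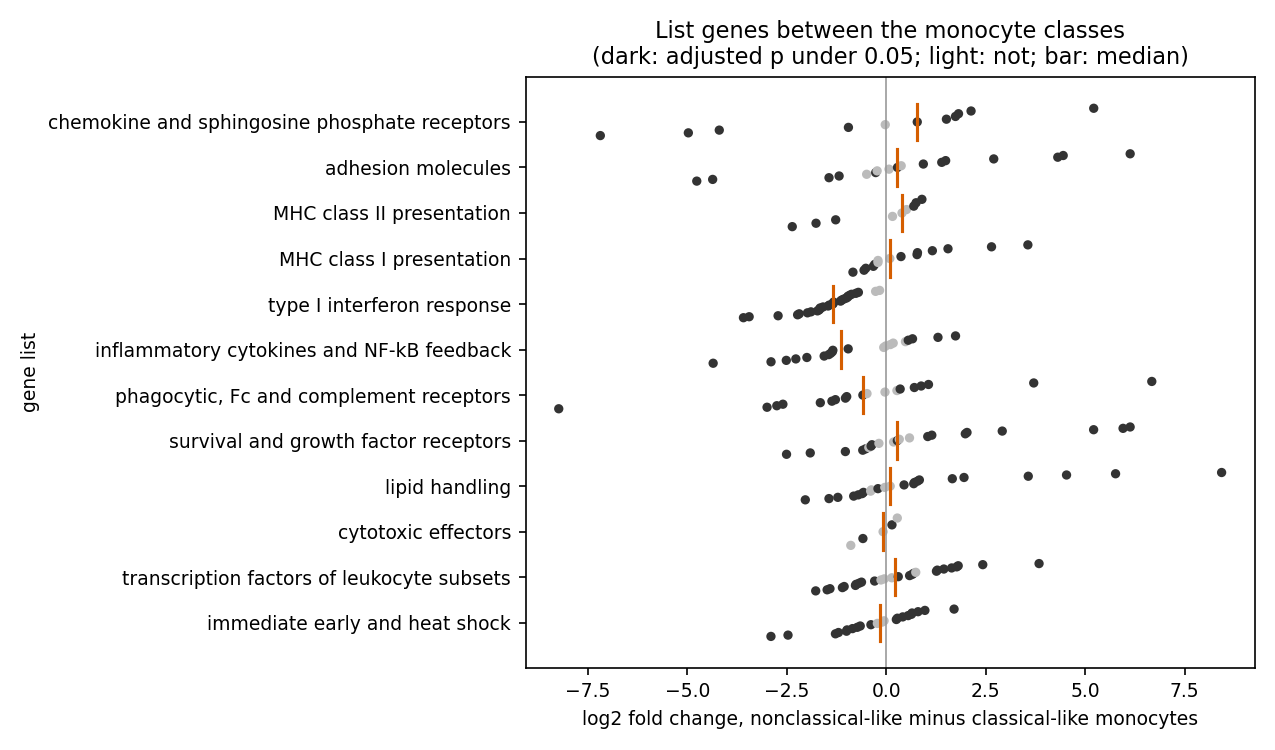
Log2 difference of nonclassical-like from classical-like monocytes for each measured member of the 12 fixed lists, dark where the adjusted p passed 0.05, with the list median as a bar. The type I interferon members lie below 0 with a median of -1.35, while the other lists have members on both sides.

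Neutrophils are granulocytes that a density gradient can leave behind, and they set the monocyte profile against another myeloid cell. Neutrophil-like cells held Cxcr2, the receptor for neutrophil-attracting chemokines, at 1079 ± 360 CPM against 0.646 ± 0.754 in classical-like monocytes (SD, n = 3; log2 difference 10.97, SE 0.32; adjusted p = 1.80e-48). They held more Il1b, which encodes interleukin 1 beta (7.34, SE 0.27), and Csf3r, the receptor for granulocyte colony-stimulating factor (4.51, SE 0.21). Classical-like monocytes held more Fcgr1, the high-affinity IgG receptor (-6.58, SE 0.39), and Cx3cr1 (-3.17, SE 0.36; adjusted p = 6.51e-13). Each differed the same way in 3 of 3 libraries. In the library labelled control 1 the counting intervals of Cx3cr1 overlapped. Neutrophil-like cells held 1 UMI there (0.0517 to 11.4 CPM), against 7.99 to 18.2 CPM in classical-like monocytes. Without control 2 Cx3cr1 was at -2.22, Fcgr1 at -5.92 and Cxcr2 at 11.71, and without control 3 Fcgr1 was at -7.32. At Leiden resolution 0.5 Cx3cr1 was at -1.77 and Fcgr1 at -5.70.

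Among chemokine and sphingosine phosphate receptors, 8 of 12 were higher in neutrophil-like cells and 4 lower (12 when adjusted over the list alone), with a median of 2.37 (adjusted p = 0.0186; adjusted p = 0.428 with an estimated correlation). S1pr1 (3.47) was higher and Ccr2 lower (-5.59, with -4.99 without control 2 and -6.41 without control 3). Inflammatory and NF-kB feedback genes were higher for 14 of 20, lower for 4 and did not pass for 2 (18 when adjusted over the list alone; adjusted p = 0.00203; adjusted p = 0.428 with an estimated correlation). They included Cxcl2 (4.89), Il1rn (4.54) and Osm (3.57). Survival and growth factor receptor genes were higher for 14 of 21, lower for 4 and did not pass for 3 (18 when adjusted over the list alone; adjusted p = 0.0144; adjusted p = 0.428 with an estimated correlation), with Bcl2l1 (2.96) higher and Csf1r (-1.71), the monocyte growth factor receptor, lower. Immediate early and heat shock genes were higher for 16 of 21, lower for 4 and did not pass for 1 (20 when adjusted over the list alone; adjusted p = 0.00203; adjusted p = 0.428 with an estimated correlation), among them Dusp1 (2.79) and Zfp36 (2.56, SE 0.20), which limits cytokine mRNA.

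Of 7 cytotoxic effector genes, 6 were higher and Lamp1 was lower (7 when adjusted over the list alone; adjusted p = 0.0144; adjusted p = 0.428 with an estimated correlation). The members that moved, Gzma (3.39, SE 0.24), Prf1 (3.52) and Nkg7 (3.16), are known from NK and T cells. Without control 3 Gzma was at 2.61 and Prf1 at 2.64, without control 2 Prf1 was at 4.19, and with doublets kept Gzma was at 2.37. T cell markers were higher in neutrophil-like cells as well, Cd3d by 3.78 and Trac by 3.35, as were the B cell marker Cd79a by 1.75 and the haemoglobin gene Hbb-bs by 3.16. Whether higher values of other genes known from lymphocytes, such as S1pr1 and class II genes, are the cells' own RNA was not tested. The cytotoxic list did not pass without control 2 (adjusted p = 0.0645). With no replicate block none of these 5 lists passed, at an adjusted p of 0.114 for immediate early and heat shock genes and 0.0949 for the other 4.

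Adhesion molecules were higher for 11 of 17, lower for 5 and did not pass for 1 (16 when adjusted over the list alone; adjusted p = 0.0930, and 0.0422 without the library labelled control 1), with the tetraspanin gene Cd9 higher by 5.86. Type I interferon genes went both ways, 15 of 30 higher, 11 lower and 4 not passing (26 when adjusted over the list alone; adjusted p = 0.360), with Rsad2 (3.93) higher and Ifi209 (-4.76) lower. Class II genes were higher for 6 of 10, lower for 2 and did not pass for 2 (8 when adjusted over the list alone; adjusted p = 0.768), with H2-DMa lower (-2.96, and -2.15 in the count split). Class I genes were higher for 5 of 15, lower for 2 and did not pass for 8 (7 when adjusted over the list alone; adjusted p = 0.497), with the immunoproteasome gene Psmb10 lower (-2.60). Phagocytic receptors were higher for 6 of 16, lower for 6 and did not pass for 4 (12 when adjusted over the list alone), with a median of 0.16, a mean of -0.70 and a test pointing up (adjusted p = 0.701). C5ar1, a complement receptor, was higher (4.13). Lipid handling genes were higher for 6 of 20, lower for 10 and did not pass for 4 (17 when adjusted over the list alone; adjusted p = 0.0930), with Npc2 lower (-2.90) and Lpl at 0 counts, at least 15.6-fold higher in classical-like monocytes and at least 6.04-fold without control 2. Transcription factors were higher for 11 of 26, lower for 13 and did not pass for 2 (25 when adjusted over the list alone; adjusted p = 0.445).

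Outside the lists, Mctp2 was higher (7.25, with 6.54 without control 2, 6.41 at Leiden resolution 0.5 and 6.60 both at resolution 2 and in the count split), and Mcub, a subunit of the mitochondrial calcium channel (-6.24), was among the largest downward. Plcb1 had 3 counts in neutrophil-like cells (ratio of classical-like to neutrophil-like level 142, counting interval 48.6 to 690) and Olfm1 had 2 (124, 34.3 to 1026). Without control 2 the Plcb1 ratio was 41.5 (14.2 to 201) and Olfm1 had 0 counts, at least 23.5-fold higher in classical-like monocytes. Without control 3 Plcb1 had 0 counts, at least 117-fold. In all, 5641 of 8417 genes differed, 2566 higher and 3075 lower in neutrophil-like cells, 4325 of them by at least 2-fold, and 6542 without the library labelled control 1. The median log2 difference of all genes tested was -0.18, and -0.16 with the other scaling, so each log2 value here stands against that centre. The smallest profile held 489251 UMIs, and 165 neutrophil-like cells came from the library labelled control 1.

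NK cells and CD8 T cells are the cytotoxic lymphocytes of blood and the lymphocyte classes in which Cx3cr1 can also be transcribed. NK-like cells held Gzma, a granule protease (log2 difference 6.59, SE 0.16), Irf8, a transcription factor, at 1518 ± 76.4 against 11.1 ± 2.82 CPM (6.64, SE 0.09), and Itgam, the integrin chain CD11b (5.89, SE 0.13), well above CD8 T-like cells. CD8 T-like cells held more Il7r, the interleukin 7 receptor (-4.15, SE 0.13), and Ccr7, which takes T cells to lymph nodes (-4.94, SE 0.14). Cx3cr1 was higher in NK-like cells by 1.96 (SE 0.20; adjusted p = 5.56e-07), at 47.1 ± 3.22 against 9.58 ± 5.12 CPM (SD, n = 3). Each differed the same way in 3 of 3 libraries.

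Of 18 cytotoxic effector genes, 12 were higher in NK-like cells, 3 lower and 3 did not pass (16 when adjusted over the list alone), with a median of 2.22 (adjusted p = 1.48e-15; adjusted p = 0.198 with an estimated correlation). Prf1, the perforin gene (4.29, SE 0.07), Gzmb (4.97) and Klrg1 (5.04) were higher and Gzmk lower (-2.95, with -3.84 without the library labelled control 1 and -1.31 without control 2). Phagocytic, Fc and complement receptors were higher for 5 of 7 and did not pass for 2 (5 when adjusted over the list alone; adjusted p = 8.77e-07; adjusted p = 0.198 with an estimated correlation). The members that moved include Fcer1g (4.93, SE 0.13, and 6.34 at Leiden resolution 2) and Tyrobp (5.66), adaptors that carry signals of NK receptors too. Type I interferon genes were lower for 19 of 29 and did not pass for 10 (21 when adjusted over the list alone; adjusted p = 1.29e-04; adjusted p = 0.198 with an estimated correlation), led by Ifi27l2a (-3.55, SE 0.08), Ifit3 (-3.28, and -4.12 without the library labelled control 1) and Oasl2 (-3.25). Adhesion molecules were higher for 10 of 19, lower for 7 and did not pass for 2 (17 when adjusted over the list alone; adjusted p = 1.97e-04; adjusted p = 0.198 with an estimated correlation). Transcription factors were higher for 15 of 27, lower for 9 and did not pass for 3 (24 when adjusted over the list alone; adjusted p = 0.0117; adjusted p = 0.465 with an estimated correlation), with Tbx21 (3.40) and Eomes (3.08) higher and Tcf7 (-2.59) and Lef1 (-3.26) lower. Inflammatory genes were higher for 7 of 14, lower for 3 and did not pass for 4 (10 when adjusted over the list alone; adjusted p = 0.00195; adjusted p = 0.272 with an estimated correlation), among them the chemokines Ccl3 (5.44) and Ccl4 (4.84).

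The other lists did not pass. Chemokine and sphingosine phosphate receptors were higher for 8 and lower for 6 of 14 (14 when adjusted over the list alone), with a median of 0.75 and a mean of -0.09 (adjusted p = 0.748). S1pr5 (4.66) was higher and S1pr1 (-3.51), the receptor for leaving lymphoid tissue, lower. Class II genes were higher for 3, lower for 3 and did not pass for 3 of 9 (6 when adjusted over the list alone), with a median of 0.15, a mean of -0.17 and a test pointing down (adjusted p = 0.748). Class I genes were higher for 4, lower for 4 and did not pass for 7 of 15 (8 when adjusted over the list alone; adjusted p = 0.756), with H2-D1 higher by 0.41, a value made uncertain by its close copies. Survival genes were higher for 7, lower for 5 and did not pass for 7 of 19 (12 when adjusted over the list alone), with a median of 0.02, a mean of -0.05 and a test pointing down (adjusted p = 0.756). Lipid handling genes were higher for 3, lower for 7 and did not pass for 8 of 18 (10 when adjusted over the list alone; adjusted p = 0.418), and immediate early genes higher for 12, lower for 4 and not passing for 5 of 21 (16 when adjusted over the list alone; adjusted p = 0.173). Outside the lists, Tnfsf12, a tumour necrosis factor family ligand, was higher (6.64), and Tdrp (-5.43), Dpp4, a surface peptidase (-4.95), and Fam169b (-4.85) were lower. Tnfsf12 was at 7.24 without control 2, 8.41 at Leiden resolution 2 and 6.02 in the count split, and Dpp4 at -4.29 in the count split. With doublets kept Tdrp was at -6.71 and Fam169b at -5.82. In all, 5790 of 10354 genes differed, 2915 higher and 2875 lower in NK-like cells, 2158 of them by at least 2-fold, and 5100 without the library labelled control 1. DESeq2 called 3690.

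CD8 and CD4 T cells are the cytotoxic and helper arms of the T cell pool. CD8 T-like cells held more Ccl5, a chemokine stored by cytotoxic cells (log2 difference 4.10, SE 0.06; adjusted p = 2.74e-20), Nkg7, a granule protein (3.82, SE 0.08), and Il2rb, a chain of the interleukin 2 and 15 receptors, at 337 ± 31.0 against 54.8 ± 10.6 CPM (2.65, SE 0.05). Within CD8 T-like cells Ccl5 was uneven, at 161 ± 8.78 CPM in cluster 3 and 8065 ± 1853 in cluster 5. CD4 T-like cells held more Maf, a transcription factor (-2.41, SE 0.09), Zbtb7b, which directs the CD4 lineage (-2.08), and Ccr4 (-3.82). Cx3cr1 was higher in CD8 T-like cells by 2.36 (SE 0.23; adjusted p = 6.48e-08), at 9.58 ± 5.12 against 1.99 ± 1.33 CPM (SD, n = 3). It was uneven within both classes. In CD8 T-like cells it was 0.754 ± 0.818 CPM in cluster 3, under the CD4 T-like mean, and 18.5 ± 7.53 in cluster 5. In CD4 T-like cells it was 0.79 CPM in cluster 1 and 7.02 CPM in cluster 11, over the summed libraries. The named genes of this comparison differed the same way in 3 of 3 libraries. In the count split Maf was at -0.55, Ccl5 at 5.84 and Cx3cr1 at 3.16, each still past the threshold, and at Leiden resolution 2 Ccl5 was at 3.38.

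Of 18 cytotoxic effector genes, 15 were higher, Srgn was lower (-0.30) and 2 did not pass (17 when adjusted over the list alone), with a median of 2.00 (adjusted p = 9.58e-33; adjusted p = 0.313 with an estimated correlation). Xcl1 (5.91), Gzmm (4.68) and Gzmb (2.87) were among those higher. Chemokine and sphingosine phosphate receptors were higher for 11 of 16, lower for 3 and did not pass for 2 (14 when adjusted over the list alone; adjusted p = 0.0528), with Ccr9 (2.73) higher and Ccr6 (-3.59) and S1pr1 (-0.79) lower. Survival genes were higher for 9 of 19, lower for 3 and did not pass for 7 (12 when adjusted over the list alone; adjusted p = 0.0528, and 0.0433 with no replicate block). Immediate early genes were higher for 6 of 21, lower for 11 and did not pass for 4 (17 when adjusted over the list alone; adjusted p = 0.0528). Junb was lower (-0.57), a call lost with all classes in 1 fit (adjusted p = 0.187, in a range from 1.18e-103 to 0.187 over the alternatives).

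Class I genes were higher for 7 of 15, lower for 2 and did not pass for 6 (9 when adjusted over the list alone; adjusted p = 0.0536), with H2-Q6 higher by 0.90 and uncertain because of its copies. Inflammatory genes were higher for 3 of 15, lower for 4 and did not pass for 8 (7 when adjusted over the list alone), with a median of -0.09, a mean of 0.37 and a test pointing up (adjusted p = 0.0536). Type I interferon genes were higher for 4 of 31, lower for 11 and did not pass for 16 (16 when adjusted over the list alone; adjusted p = 0.0653), with Ifi27l2a lower (-0.76). Phagocytic receptors were higher for 3 of 10, Fcer1g (1.59, and 0.25 at Leiden resolution 2) among them, and did not pass for 7 (3 when adjusted over the list alone; adjusted p = 0.0653). Several of these lists passed when 1 library was left out. Without the library labelled control 1 they were chemokine receptors, class I and immediate early genes (adjusted p = 0.0306 each), survival genes (0.0409), and interferon genes and phagocytic receptors (0.0499 each). Without control 2 they were chemokine receptors (0.0396), interferon genes (0.0411) and immediate early genes (0.00769). Without control 3 they were chemokine receptors (0.0107), class I genes (0.0486) and immediate early genes (0.0165).

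Adhesion molecules were higher for 10 of 19, lower for 6 and did not pass for 3 (17 when adjusted over the list alone; adjusted p = 0.155), with Itgae, which binds E-cadherin, higher (3.39, and 2.74 without the library labelled control 1) and Itga6 lower (-1.24). Class II genes were higher for 2 of 9, H2-Oa (1.78) and H2-DMa (0.53), and did not pass for 7 (2 when adjusted over the list alone), with a median of -0.02, a mean of 0.24 and a test pointing up (adjusted p = 0.244). Lipid handling genes were higher for 3 of 20, lower for 8 and did not pass for 9 (11 when adjusted over the list alone; adjusted p = 0.151), with Lipa, lysosomal acid lipase, lower (-1.13). Transcription factors were higher for 8 of 29, lower for 14 and did not pass for 7 (23 when adjusted over the list alone), with a median of -0.18, a mean of 0.03 and a test pointing down (adjusted p = 0.3003). Eomes (4.52) and Runx3 (1.27) were higher, with Eomes at 5.26 without the library labelled control 1 and at 3.93 without control 2. Outside the lists, Lcn4 (3.60) and Racgap1 (3.28) were higher, and St8sia6, a sialyltransferase (-3.96), Tesc (-2.44) and Hif1a, the hypoxia factor (-2.30), were lower. In the count split Lcn4 was at 2.93, St8sia6 at -2.35 and Tesc at -1.74. In all, 3799 of 10652 genes differed, 1831 higher and 1968 lower in CD8 T-like cells, 672 of them by at least 2-fold, and 3161 without the library labelled control 1. The count was 1819 with DESeq2, 1638 with no replicate block, 1943 with all classes in 1 fit and 2503 with the counts split between clustering and testing.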

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

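The tests on the library labelled control 1 and on other splits of the profiles were chosen only after the result was seen. The others below were set beforehand, although the leading genes Aif1 and Tmem176b of cluster 12 had been seen.

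Cells left unnamed entered no comparison. In 10 of their 13 clusters the lower counting bound of Cx3cr1 lay above the upper bound of the B-like background, 1.02 CPM over the libraries, and the other 3 held no UMI of the gene. Cluster 12 had 186 CPM (95% exact Poisson interval 177 to 196; 1496 cells). Cluster 15, led by the platelet genes Ppbp and Clec1b along with F13a1, had 69.1 CPM (59.3 to 79.9; 378 cells). Cluster 21, led by Vcan, F13a1 and Chil3, had 54.97 CPM (43.2 to 69.0; 159 cells, 146 of them from control 2), and 25.4 CPM without control 2. Cluster 19, led by haemoglobin genes, had 11.2 CPM (6.24 to 18.4; 196 cells), and cluster 16, also led by haemoglobin genes, had 3.22 CPM (1.04 to 7.51; 300 cells), from 5 UMIs, and did not lie above the background whichever library was left out. Of the smaller clusters, cluster 30, led by Ace, Treml4 and Cd36, had 285 CPM (208 to 382; 27 cells), and cluster 28, led by haemoglobin genes, had 89.3 CPM (57.2 to 133; 33 cells). Cluster 31, led by Fcgr1 and Trem2, had 56.8 CPM (22.8 to 117; 19 cells), with 92.5 CPM without the library labelled control 1, and without control 2 it had 1 UMI and did not lie above the background. Cluster 27, led by Prg4, C1qa and C1qb, had 29.0 CPM (17.5 to 45.3; 61 cells) and 18.4 CPM without control 2. Cluster 24, led by Ifi211, Vcan and F13a1, had 19.7 CPM (11.5 to 31.5; 95 cells) and 11.6 CPM without control 2. These clusters also scored for a second class. Cluster 28 scored 7.58 for erythroid cells and 2.97 for classical monocytes, and cluster 19 scored 7.42 and, for T cells, 2.55. Clusters 21 and 30 scored best for neutrophils, with 4.84 for classical and 4.76 for nonclassical monocytes. Which cells in such a cluster hold Cx3cr1 was not tested.

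Cluster 12 held markers of both monocyte classes, and of 1676 genes that differed at least 2-fold between the classes, 1513 (90.3%) lay between their levels. Doublets of the 2 classes would leave no gene outside both levels, but 14 genes lay at least 2-fold outside. Among these, Aif1, Tmem176a and Tmem176b had been used for clustering, and Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1 come from the class II list. B-like or dendritic-like RNA would need markers at 0.5 of the level the cluster's Cd74 asks for, but the higher median was 0.163 (B-like 0.0588), although the dendritic marker Naaa reached 3.07. By their own thinned counts 67.8% of the cluster's cells lay between the bounds of both classes (59.2%, 68.4% and 69.3% per library). The rest were mostly within the classical-like range. In the median cell 33.8%, 32.4% and 33.9% of class-differing UMIs came from genes higher in nonclassical-like monocytes. The classical-like bound was 30.7%, 26.6% and 25.3%, and the nonclassical-like bound 55.1%, 56.0% and 57.1%. The same clustering had set these cells apart from both classes before the bounds were drawn. The values therefore cannot tell an in-between kind from an edge of the classical-like cells, and cells that each resemble 1 class stay open. A test by Leiden resolution 2 put 0% of the cells in a named class, but this was fixed by the naming, since 1495 of the 1496 cells fell in 1 cluster with scores of 4.02 and 3.06 for the 2 classes, and a low value there was wrongly taken beforehand to speak against a mixed cluster. Cells passing from the classical to the nonclassical state may make up this cluster, a hypothesis that the design gives no group to test.

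Cx3cr1 was low in the monocyte-like cells of the library labelled control 1. A loss of the gene's reads from the whole library would lower NK-like cells too, but these held 48.2 CPM, within the range of control 2 and 3. Cells of another named class in place of most nonclassical-like cells would bring down the 22 genes at least 4-fold above every other named class in control 2 and 3 that neither clustering nor naming used, but these stood at a median of 86.8% of the lower of the others (lowest 63.7%), while for classical-like cells this stays open, with 4 such genes at a median of 51.8%. A wrong label on a library of an animal deleted in monocytes may account for the nonclassical-like level, 1.38% of the lower of the others, but is left open for classical-like monocytes, which kept 16.1% of the lower of the others, at 12.4 CPM against 0.0477 in B-like cells, as the extent of the deletion is not given in the sources used here. No partner out of place was tested, as the knockout libraries were not analysed here, and reduced transcription of the gene in that animal stays open, as no biological explanation was tested.

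The type I interferon list was lower in nonclassical-like monocytes. A small subset of classical-like cells with very high levels would leave the median cell unchanged, but the median thinned cell held 6, 7 and 7 UMIs of the list in classical-like against 2, 2 and 2 in nonclassical-like monocytes, a lowest ratio of 3. These UMIs are summed over the list, so its most abundant genes weigh most. A subset with high levels of the less abundant genes stays open. The list's call was lost with an estimated correlation (adjusted p = 0.788), so correlation among its genes stays open. No biological explanation was tested.

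The 6 profiles of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many genes. With edgeR the real splits called 5121, 5641, 5790 and 3799 genes for monocytes, neutrophil-like cells, NK-like cells and T-like cells in the order of the report, and the highest of the other splits called 0. At an unadjusted p under 0.05 the real splits had 5571, 5838, 6266 and 4648 genes and the highest others 160, 50, 42 and 170. Of the 9 other splits, 3 also part all 3 pairs, and they called 0 genes with edgeR, with at most 46, 1, 5 and 34 at an unadjusted p under 0.05. All 9 mix the classes within a side, so the class difference adds to their spread, and their 0 calls say little. With the library as a block some of the 10 splits amount to the same test. DESeq2 was not run on the splits.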

How the results depend on the processing

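The fit with no replicate block for gene lists was chosen only after the result was seen; the other alternatives were planned. Of 1589 values of 183 results under alternatives, 1517 were counted as unchanged, 17 lost the call, 18 gained one, 37 moved and 0 reversed. Unchanged values kept their direction and side of the threshold or, with no test, their size. A list could count as reversed only if it was called, and a list not called whose direction flipped counted as moved. Class II genes flipped so in the monocyte and neutrophil-like comparisons without the library labelled control 1. Lists were not tested again with RLE scaling, and those not called counted as unchanged there. Among named genes, 382 of 390 pairs of gene and alternative kept their direction and side of the threshold in the monocyte comparison, 234 of 234 for neutrophil-like against classical-like, 247 of 247 for NK-like against CD8 T-like and 233 of 234 for CD8 against CD4 T-like. The exceptions were Cx3cr1, Srgn and Junb, given in the report. The fold itself moved by over 1.5 times in 19, 21, 7 and 8 of these pairs, from 15, 9, 5 and 7 genes.

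Counts of differing genes moved by over 1.5 times with DESeq2 in NK-like against CD8 T-like cells (3690) and in CD8 against CD4 T-like cells (1819). In the latter they also moved with all classes in 1 fit (1943) and with the count split (2503). The cause was not tested. Leaving out 1 library gave 3669 to 5994 genes in monocytes, 3976 to 6542 in neutrophil-like against classical-like, 5044 to 5275 in NK-like against CD8 T-like and 3161 to 3475 in CD8 against CD4 T-like cells. Lists called then numbered 1 to 5, 4 to 6, 6 to 6 and 4 to 7 in the same order, and Cx3cr1 was higher in nonclassical-like monocytes than in 8 to 12 classes. With an estimated correlation limma's camera called 0 lists in each of the 4 comparisons, with 0, 0, 2 and 1 lists at an unadjusted p under 0.05.

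Both classes of a comparison come from the same libraries, so the block pairs them. With no replicate block the CD8 against CD4 T-like comparison fell to 1638 genes, and 4420, 5648 and 4802 were called in the others. Lists called with no replicate block were 5 in monocytes, 0 with camera in neutrophil-like against classical-like cells and 2 in CD8 against CD4 T-like cells; the NK-like comparison had 6 as before. Among named genes it ended the Cx3cr1 and Srgn calls of the monocyte comparison and no other.

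At Leiden resolution 2 CD4 T-like cells made up 12.5% and gamma-delta T-like cells 2.32%. CD8 T-like cells made up 11.9% there and clusters named T-like 5.66%. Unnamed cells averaged 5.03% in the main setting, 1.94% at resolution 0.5 and 15.3% with doublets kept. The cause was not tested. No cluster was named plasmacytoid dendritic-like at either other resolution, with the stricter cell filter or with doublets kept, and none conventional dendritic-like at resolution 2, regulatory T-like at resolution 0.5 or basophil-like with the stricter cell filter, so these shares have no value there. The comparison of neutrophil-like cells had the lowest depth and the lowest recovery: its smallest profile held 489251 UMIs, and the simulation recovered 15.4% of genes changed 1.5-fold. Whether depth set the recovery was not tested.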

Other observations

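All tests named in this part were chosen only after the result was seen, except those on cluster 12 given above, and the values below carry no test of their own unless an adjusted p is given.

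Cluster 12, with markers of both monocyte classes, held Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1 of the class II list at higher levels than either class. Cd74 was higher by 2.06 on the log2 scale than in nonclassical-like and by 2.91 than in classical-like monocytes, H2-Aa by 2.83 and 3.51, H2-Ab1 by 2.97 and 3.35, and H2-Eb1 by 2.82 and 3.58. C1qb, a complement component (4.01 and 3.56), the peptide-loading gene H2-DMb1 (3.41 and 1.64) and Batf3, a transcription factor of dendritic cells (3.18 and 1.12), were above both as well, and Sort1 was below both (-1.39 from nonclassical-like monocytes). Ly6c2 and Ccr2 lay between the classes, at 4.41 and 4.18 above nonclassical-like and at -1.16 and -0.81 from classical-like monocytes. Nr4a1 did too, at -0.57 and 1.19. Cx3cr1 was higher than in classical-like monocytes by 1.36, but in 2 of 3 libraries, and did not differ past the threshold from nonclassical-like monocytes (-0.49, adjusted p = 0.05997, edgeR). Its Cx3cr1 level was 10.8 CPM in the library labelled control 1, against 12.4 CPM in classical-like and 4.82 CPM in nonclassical-like monocytes there, with overlapping counting intervals, and 207 and 229 CPM in control 2 and 3. Its cells held a median of 6740, 5668 and 3670 UMIs, against 6635.5, 5765 and 4206 in classical-like and 3883, 3315.5 and 2159 in nonclassical-like monocytes.

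CD8 T-like cells came from clusters 3 and 5, described here by genes of the fixed lists, which were not used for clustering. Cx3cr1 was 0.754 ± 0.818 CPM in cluster 3 and 18.5 ± 7.53 in cluster 5 (SD, n = 3). Cxcr3, a receptor for interferon-induced chemokines, was 2.86 ± 0.730 and 43.7 ± 11.9 CPM, Eomes 7.37 ± 2.52 and 51.5 ± 19.0, Tbx21 0.421 ± 0.157 and 11.5 ± 3.11, and the granule protease gene Gzmm 1.96 ± 0.888 and 66.2 ± 2.96. Ccr7 was 581 ± 22.1 and 242 ± 20.1 CPM. Cluster 5 held 35.7%, 54.2% and 41.9% of CD8 T-like cells in control 1, 2 and 3.

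The library labelled control 1 had the lowest level of several other genes in most classes. Fos in B-like cells was 102, 387 and 337 CPM in control 1, 2 and 3, and lowest in the library labelled control 1 in 7 of 7 classes. Hbb-bs in B-like cells was 6.40, 943 and 526 CPM, likewise in 7 of 7. Ccr2 in classical-like monocytes was 565, 1274 and 1262 CPM, and lowest in the library labelled control 1 in 6 of 7 classes. S100a8 was lowest there in 5 of 7, but not in neutrophil-like cells, which held the most of it (83769, 82724 and 68784 CPM). Several other classes held little of these genes, as with Ccr2 in B-like cells (1.43, 7.95 and 10.9 CPM). Whether such levels are the cells' own RNA was not tested.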
